A study of Homo sapiens with 12 samples.

How the data were processed

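The series holds 12 RNA sequencing libraries of DLD-1 colorectal cancer cells and of the EVs they release, 3 per group in 4 groups: cell control, EV control, cell RNase R and EV RNase R. Per the labels, total RNA libraries were made with a stranded kit after ribosomal RNA depletion, and RNase R treatment (1 µg of RNA, 1 unit, 30 minutes, 37 °C) preceded the RNase R libraries. Control libraries were used for linear RNA and RNase R libraries for circRNAs. Groups follow the sample titles. The titles and the treatment field of 2 cell samples disagree: the third control library carries RNase R in that field, and the third RNase R library carries Control. The titles go with the kind of file deposited for each sample, so no sample was moved. Titles number the replicates, but nothing says that they are separate cultures, so p-values measure the spread between samples, which may be technical.

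Per the submitters' processing notes, the authors used kallisto 0.44.0 and STAR 2.7.10b with the hg38 genome; the circRNA caller is not given in the sources used here. Per the file headers, the control samples have tables of kallisto with an estimated count, a length, an effective length and a TPM for each of 227442 transcripts, 1 table per lane and sample (12 in all). The deposited circRNA tables list a back-splice read count per circRNA position, also 1 per lane (12 in all). The length and effective length in nt are as deposited by the authors, and the lanes of a sample were summed. In each of the linear tables, 20 lines are emptied, and 16 genes lie beside such a line. These lines, and the items on them, are not reported here.

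Estimated counts were summed over the transcripts of a gene (60609 genes) and rounded. Gene and transcript types come from the names in the files and GENCODE 29, with which 83.4% of the transcripts match. Depth was 42220923, 39856520 and 38034087 counts in the cell control libraries and 25633231, 13311010 and 18140126 in the EV control libraries. Back-splice reads numbered 73241, 61271 and 134366 in cells and 37829, 59526 and 35072 in EVs. Of the distinct circRNAs, 58.1, 57.1 and 25.2% had a single read in cells, and 50.0, 41.1 and 32.6% in EVs. Agreement between lanes was near counting error (chi-square per degree of freedom 1.25 to 1.39 for genes, 0.88 to 1.22 for circRNAs), whereas replicates of a group differed by more (12.5 to 136 and 2.18 to 3.57). Counting error alone would therefore understate the error of any fold change. Correlations of log2 CPM between replicates were 0.952 to 0.984 in cells and 0.915 to 0.941 in EVs for genes, and 0.726 to 0.765 and 0.536 to 0.652 for circRNAs. The third cell control library, 1 of those with conflicting labels, correlated at 0.984 with the second and 0.952 with the first. The third cell RNase R library, whose labels also conflict, correlated at 0.741 with the second and 0.726 with the first.

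Differences were tested with edgeR 4.0.16 (quasi-likelihood, robust, TMM factors, Benjamini-Hochberg adjusted p under 0.05, two-sided) in R 4.3.3, after its expression filter with a minimum count of 10 (total 15) for genes and of 5 (total 15) for circRNAs. TMM factors were 1.295, 1.328 and 1.351 in cells and 0.681, 0.824 and 0.767 in EVs. CPM values are scaled by these factors, and errors are the SD over 3 libraries, or the SE of the fit for a log2 fold change. Against a group with 0 counts, a fold is a bound from a floor of 3 counts over the group. Gene lists, 28 in number, were tested against all other tested genes with camera of limma 3.58.1 (preset correlation 0.01 and an estimated correlation) and with fry, adjusted over the lists, and list members also with an adjustment over the list alone. Shares and values per library were compared with exact two-sided permutation tests, whose smallest p at 3 against 3 is 0.1. Correlations across genes or circRNAs use 100000 permutations (10000 in the alternatives); their features are not independent of each other, so these p values are too small. Tables were handled with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.

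The circRNA tables were expected to give exon sizes but do not. Positions were matched to exon boundaries of GENCODE 29 instead, which placed 56172 of 57616 circRNAs (97.5%) in a transcript, and spliced length was taken as the sum of the exons between the back-splice sites. Introns retained inside a circRNA would not be seen. Sharing of sequence was measured as the percentage of a gene's 31-mers present in other genes. Distinct circRNAs were counted after thinning each library to 35072 reads, as the mean of 20 draws.

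Genes named in the text follow a rule fixed with the tests and lists before the data were examined. Among genes with an adjusted p under 0.05, a mean CPM of 20 or more and groups that do not overlap, it takes the 10 highest and 10 lowest mRNA or lncRNA genes and the 3 highest and 3 lowest of other types. From each list it takes the 2 members with the smallest p and the most abundant 1, and among circRNAs the 8 highest, 8 lowest and 5 most abundant. Other members named beside a list's counts were chosen after their values were seen. The tests were tried on simulated data with known changes and 3 libraries per group. In these data 200 features were changed, as many up as down, so they lack the large shift in RNA composition between EVs and cells. Their rates of recovery and of false calls need not hold for the real data. Of genes changed 2-fold, 22% were recovered, and 68.8% of those changed 4-fold, with 4 false among 90 calls; for circRNAs it was 8.3% and 52.4%, with 0 false among 51 calls.

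Alternatives were RLE factors, no factors, DESeq2 1.42.0, limma on log2(TPM + 1), other filters (none, a mean CPM of 10 or more, protein-coding genes only, without mitochondrial genes and genes under 300 nt), each lane alone, a replicate block, a fold change minimum, back-splice reads summed per host gene, other lengths, and leaving out each library in turn. Nothing was compared between control and RNase R libraries, since these have different kinds of table.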

Results

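EVs of DLD-1 colorectal cancer cells carried a far larger share of short structured RNAs than the cells. 7SL RNA (RN7SL1, RN7SL2), the RNA of the signal recognition particle, took 28.5 ± 2.34% of the estimated counts in EVs and 2.14 ± 0.488% in cells (mean ± SD, n = 3 libraries per group). RPPH1 and RMRP, the RNAs of RNase P and RNase MRP, together took 3.07 ± 0.487% in EVs and 0.634 ± 0.0810% in cells. Other shares were lower in EVs: lncRNA genes took 1.73 ± 0.0550% against 8.19 ± 1.90%. Most of this share in cells was the lncRNA gene MIR663AHG alone (0.272 ± 0.0627% against 5.29 ± 1.67%). Transcripts annotated as retained introns took 2.09 ± 0.120% against 5.45 ± 0.205%, and mitochondrially encoded genes 0.378 ± 0.050% against 2.04 ± 0.738%. Genes of the rRNA type took 0.0209 ± 0.00259% against 0.213 ± 0.0606%. Nuclear protein-coding genes held 63.6 ± 2.62% of EV counts and 83.4 ± 2.50% of cell counts. For each of these shares the 3 EV libraries lay outside the range of the 3 cell libraries, and the exact two-sided permutation test gave p = 0.1, the smallest it can give at this size, so no share passed 0.05. On the TPM scale, which divides by length, the share of misc_RNA genes (mostly 7SL RNA) was 68.7 ± 3.79% in EVs and 11.1 ± 2.41% in cells. That of miRNA genes, which are very short, was 0.508 ± 0.112% in EVs and 33.1 ± 7.93% in cells on this scale.

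**Figure D1:**
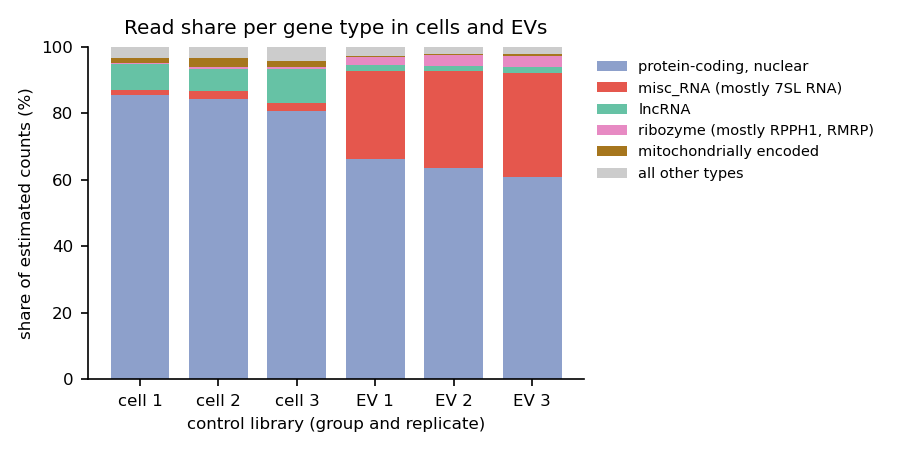
Stacked bars give the share of estimated counts (%) per gene type in each of the 3 cell and 3 EV control libraries, with mitochondrially encoded genes kept apart from the other types. 7SL RNA, which makes up most of the misc_RNA bar, takes 2.14 ± 0.488% in cells and 28.5 ± 2.34% in EVs (mean ± SD).

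Among genes with a mean CPM of 20 or more and groups that did not overlap, the mRNAs with the largest log2 fold changes after HBA1 were those of TRAK2, RAB13 and NET1. TRAK2, a kinesin adaptor, rose from 19.7 ± 10.5 to 3495 ± 1036 CPM (log2 fold change 7.47), RAB13, a small GTPase, from 12.4 ± 2.76 to 2139 ± 558 CPM (7.43), and NET1, a RhoA exchange factor, from 66.9 ± 11.4 to 8397 ± 2407 CPM (6.97). NIN (ninein, a centrosome protein, 6.61), UACA (5.82), IGIP (5.69), RASSF3 (5.58), the dynein adaptor BICD2 (5.35) and PITPNM3 (5.18) followed. Outside mRNA and lncRNA genes, RN7SL2 (4.72), the pseudogene C22orf46 (4.60) and RN7SL1 (4.28) were highest under the same limits. HBA1, coding for haemoglobin alpha, had the largest log2 fold change of the genes named by the rule (7.65 ± 0.99 SE), from 0.203 ± 0.204 to 41.3 ± 30.1 CPM; without cell replicate 1 it did not pass. Of its 31-mers, 82.4% occur in other genes, HBA2 being the largest sharer, so the split of reads between them is uncertain.

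Of the 10 lowest mRNA or lncRNA genes, 6 were lncRNA genes. The lncRNA genes AC103702.1 (-4.32), MIR663AHG (-3.45), LINC00273 (-3.18), AC107959.1 (-2.69), AL627309.5 (-2.47) and AC092279.1 (-2.45) were the lowest with the protein-coding IFITM10 (-4.27), ANKRD30BL (-3.15), HOXB4 (-2.71) and the glycine transporter gene SLC6A9 (-2.62). AC103702.1 overlaps HOXB4; 17.4% and 14.6% of their 31-mers occur in other genes, and each is the largest sharer of the other. MIR663A (-4.04) lies within MIR663AHG. The gene entries CR392039.1 and FP671120.2 (both -4.13) have the sequence of MIR3687 and share 100% of their 31-mers, so their reads cannot be separated. The copy at 8208844 on chromosome 21 lies inside RNA45SN2, the 45S rRNA gene that starts at 8205988, and the span of ANKRD30BL on chromosome 2 holds an 18S rRNA pseudogene of 1849 nt. ANKRD30BL shares 48.7% of its 31-mers with other genes and is uncertain for that reason.

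**Figure D2:**
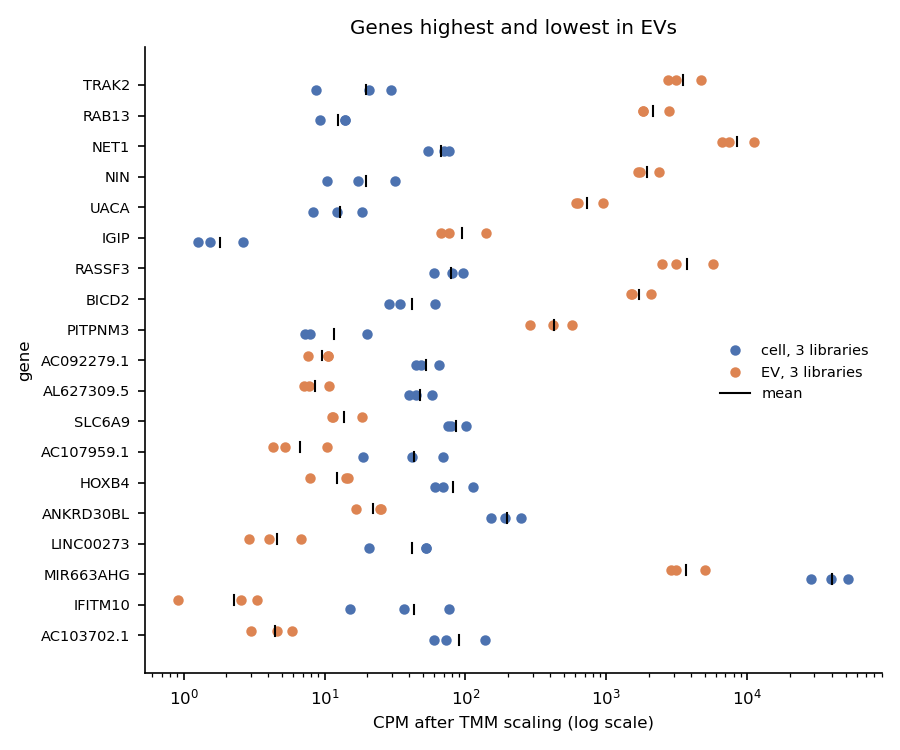
Points give CPM after TMM scaling (log axis) of 19 mRNA and lncRNA genes chosen by fold change in each of the 3 cell and 3 EV control libraries, and ticks give group means; HBA1 is left out because 1 cell library holds 0 counts. NET1 lies between 54.1 and 76.0 CPM in cells and between 6655 and 11144 CPM in EVs.

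Of 22974 genes tested, 8048 differed at an adjusted p under 0.05 (edgeR quasi-likelihood, two-sided), 3592 higher and 4456 lower in EVs; 2395 and 3711 of them differed by 1 or more on the log2 scale. Protein-coding genes went both ways (3118 higher and 2157 lower of 14513, median log2 fold change 0.02). Far more lncRNA genes were lower than higher (1559 against 250 of 5931, median -1.15), as were pseudogenes (376 against 78 of 1314, median -1.06) and, by number, misc_RNA genes (75 against 28 of 264), although 7SL RNA rose. Small nuclear RNA genes (46 higher and 19 lower of 93, median 1.51) and snoRNA genes (22 and 6 of 127, median 0.65) were more often higher than lower, but the snoRNA median was -0.17 without scaling factors and both medians were negative on log2(TPM + 1) (-0.96 and -1.86). In 12500 genes (54.4%) the 3 EV values and the 3 cell values did not overlap, against 10% by chance. Counts of genes are not counts of independent events, because all fold changes share the same 6 libraries and 1 set of scaling factors.

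The zero point of these fold changes depends on the scaling. With TMM factors the median of all tested genes was -0.30. Without factors it was -1.11, a shift of -0.81, and 1104 genes were higher and 11326 lower. With limma on log2(TPM + 1) the shift was -0.63, 196 genes were higher and 19243 lower, and 1784 of the calls changed direction. On the TPM scale 7SL RNA holds most of the EV total, which presses the values of all other genes down. In cells miRNA genes hold 33.1% of the TPM total, which presses the cell values of other genes down. Fold changes below are relative to the TMM scale, and a list whose median changes sign without factors is named where it is described. On log2(TPM + 1) every list median was negative except those of the small structured noncoding RNAs (0.11) and the spliceosomal small nuclear RNAs (0.20). Leaving out cell replicate 2 gave 5260 genes, 3510 higher and 1750 lower, and leaving out cell replicate 3 gave 5949, 3856 higher and 2093 lower.

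mRNAs of the translation machinery were higher in EVs. All 79 cytosolic ribosomal protein genes tested rose (median 1.57, range 0.66 to 2.59), led by RPL14 (2.59), RPL12 (2.44) and RPL37 (2.37), with RPS2 the most abundant (1754 ± 293 to 6775 ± 223 CPM). Of 21 translation factors and other messages with a 5' terminal oligopyrimidine tract (TOP mRNAs), 15 rose, none fell and 6 did not pass (median 0.97; NACA 1.92, EIF3E 1.77, EEF1A1 1.14), or 19 when adjusted over the list alone. Both medians stayed positive without factors (0.76, 66 higher and 0 lower, and 0.16, 7 and 2). On log2(TPM + 1) both were negative (-0.22, 1 higher and 16 lower, and -0.84, 0 and 11). The 13 mitochondrially encoded mRNAs went down: 12 fell and MT-ATP8 did not pass (median -1.41; MT-CO3 -2.21, MT-CO2 -1.94, MT-CO1 -1.58), and the sign held in every scaling tried. The 2 mitochondrial rRNA genes, MT-RNR1 and MT-RNR2, both passed (median 1.56), MT-RNR1 narrowly (edgeR adjusted p = 0.0499). Only 1 of them passed with RLE factors or without factors, and on log2(TPM + 1) neither passed and their median was -0.18. The libraries were depleted of ribosomal RNA, and whether depletion worked equally in cells and EVs was not tested. Nuclear genes for the same respiratory complexes went up (29 of 47 higher, 0 lower, median 0.82; UQCRB 1.62, NDUFB7 1.57), though without factors the median was 0.01 with 4 higher and 10 lower. Mitochondrial ribosomal protein genes, made from nuclear mRNAs, were higher in 20 of 30 cases with none lower (median 0.70; MRPL41 1.83, MRPL51 1.33), and this median turned to -0.10 without factors, with 3 higher and 5 lower. Their most abundant member, MRPL37 (0.68), had -0.12 without factors and also lost its call without the filter (adjusted p = 0.0536), at a mean CPM of 10 or more (0.0527) and without EV replicate 1 (0.0774) or 2 (0.0777). EEF1A1 (0.32) lost its call without factors. By camera with a preset correlation of 0.01 the adjusted p was 6.79e-34 for ribosomal proteins, 1.36e-08 for the TOP mRNAs, 0.000273 for mitochondrial mRNAs, 3.91e-11 for respiratory genes and 1.05e-07 for mitochondrial ribosomal proteins. With an estimated correlation none of the 5 passed (adjusted p = 0.437, 0.437, 0.526, 0.474 and 0.474).

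Small noncoding RNAs that work in ribonucleoproteins were enriched. Of 10 small structured RNAs, 7 were higher and 0 lower (median 2.23): the 3 7SL genes (RN7SL2, RN7SL1, and RN7SL3 at 4.07), RPPH1 (3.34), RNY1 (2.25) and RMRP, which has 2 gene entries (2.21 and 1.84). RN7SK, which controls transcription elongation in the nucleus, did not pass (0.41). Of 21 spliceosomal small nuclear RNAs, 18 were higher and 0 lower (median 2.29), among them 4 copies of U1 (RNU1-1 to RNU1-4, 3.20 each). The U1 copies share 100% of their 31-mers and count as 1 signal, copies of U6 likewise have identical summed counts (23 in cells and 70 in EVs for RNU6-1, RNU6-2 and RNU6-9, 12 and 36 for RNU6-7 and RNU6-8), and RN7SL1 shares 100% of its 31-mers with other genes. Both medians stayed positive without factors (1.41 and 1.47). The adjusted p by camera was 1.05e-07 for the small structured RNAs and 3.91e-11 for the spliceosomal RNAs. With an estimated correlation neither passed (adjusted p = 0.437 each).

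Several nuclear lncRNAs were lower in EVs, whereas most small nucleolar RNA host genes were higher. Of 10 nuclear lncRNAs, 6 were lower and 0 higher (median -1.09): LINC-PINT (-2.02), SNHG14 (-1.67), FTX (-1.44), PVT1 (-1.40), MALAT1 (-1.25, 2469 ± 294 to 1036 ± 144 CPM) and KCNQ1OT1 (-0.92). NEAT1 (-0.36) and TUG1 (-0.46) did not pass, nor did MIAT (0.04) and MEG3 (2.23, adjusted p = 0.0558). The list as a whole missed the threshold (camera adjusted p = 0.0511) but passed in 9 of 14 alternative settings, where the adjusted p ranged from 0.000427 to 0.221. Of 16 small nucleolar RNA host genes and cytoplasmic lncRNAs, 11 were higher, 1 lower (CYTOR, -0.92) and 4 did not pass (median 0.88; SNHG8 1.69, GAS5 1.47, SNHG29 0.98; camera adjusted p = 9.83e-06), with a median of 0.07 without factors (5 higher and 2 lower), where SNHG29 (0.17) lost its call. With an estimated correlation the adjusted p = 0.437 for both lists, and the difference between them was not tested.

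Most listed mRNAs for mitotic proteins were also higher in EVs. Of 24 mitotic genes, 21 were higher and 0 lower (median 1.33, 0.51 without factors with 10 higher and 1 lower; camera adjusted p = 3.91e-11, but 0.474 with an estimated correlation), led by the kinesin CENPE (3.94), the midbody protein ANLN (3.92) and CENPF (3.49); AURKB, UBE2C and PLK1 did not pass. In a fixed list of 40 very long mRNAs, 23 were higher and 2 lower, KMT2D (-1.41) and UBR4 (-0.82), with a median of 0.63 that turned to -0.18 without factors, where 10 were higher and 14 lower (camera adjusted p = 1.3e-07, but 0.474 with an estimated correlation). MACF1 (4.34, from 274.7 ± 50.1 to 5558 ± 1008 CPM) and DST (3.36), both linkers of microtubules and actin, were the highest of these. Cytoskeleton genes followed (10 of 26 higher, VCL lower, median 0.51; MYL12B 1.43, TMSB10 1.06; camera adjusted p = 0.000154, but 0.53 with an estimated correlation), and without factors their median was -0.30 with 1 higher and 7 lower, and TMSB10 (0.26) lost its call.

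Lists for RNA handling, protein turnover, histones and immediate early genes had medians of 0.48 to 0.70, and each of the medians in this paragraph changed sign without factors. RNA-binding proteins implicated in sorting RNA into vesicles were higher in 10 of 18 cases and lower in none (median 0.70, -0.12 without factors), with YBX1 (2.07), SSB (1.81) and HNRNPA2B1 (1.45) at the top and IGF2BP1 (-1.14) not past the test. Serine/arginine-rich splicing factors and partners were higher in 13 and lower in 2 of 29 (median 0.55, -0.26 without factors): RBM25 (3.40) and SF3B1 (1.41) rose, U2AF1 (-1.63) and CCNL2 (-0.74) fell. Proteasome genes were higher in 14 of 31 and lower in none (median 0.48, -0.33 without factors; PSMA3 1.36, PSMC6 1.25). Replication-dependent histone genes were higher in 7 of 23 (median 0.56, -0.25 without factors; HIST1H1E 1.40), and immediate early genes in 7 of 26 with IER3 (-0.79) lower (median 0.51, -0.30 without factors; FOS 3.07, FOSB 1.65). Without factors HIST1H1E (0.60, adjusted p = 0.0875) lost its call, and the numbers higher and lower were 3 and 6 for sorting proteins, 2 and 10 for splicing factors, 2 and 12 for the proteasome, 0 and 4 for histones and 2 and 12 for immediate early genes. The adjusted p by camera was 0.000498 for sorting proteins, 0.000826 for splicing factors, 8.26e-06 for the proteasome, 8.07e-05 for histones and 0.00187 for immediate early genes. With an estimated correlation none of the 5 passed (adjusted p = 0.53, 0.53, 0.526, 0.526 and 0.437).

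Genes of the ER and of cholesterol synthesis had more members lower than higher. Of 20 endoplasmic reticulum (ER) chaperone genes, 10 were lower and 2 higher (median -0.48): HYOU1 (-1.71), SEC61A1 (-1.43), PDIA3 (-1.03), PDIA4 (-0.93) and P4HB (-0.75) fell, HSP90B1 (0.63) and SEC61B (0.89) rose. Camera missed the threshold (adjusted p = 0.12), whereas fry, which tests whether the list moves against 0 and not against other genes, gave 0.0141. Of 22 cholesterol synthesis genes, 6 were lower and 2 higher (median -0.25; DHCR7 -1.05; HMGCS1 0.79, IDI1 1.01; camera adjusted p = 0.689). The genes for EV tetraspanins and biogenesis proteins did not move together (7 higher, 3 lower, 16 not past the test; median 0.27, -0.54 without factors with 3 higher and 11 lower; camera adjusted p = 0.0218, direction up, and adjusted p = 0.53 with an estimated correlation). CD81 (-0.94), CD63 (-0.90) and VPS37B (-0.73) fell, whereas RAB27B (2.24), ANXA1 (2.12), ANXA2 (1.88), PDCD6IP (0.92) and SDCBP (0.91) rose.

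Tissue and pathway markers showed no common direction. Among 21 intestinal epithelial genes, GPA33 (-2.98), CLDN4 (-1.19), CDH1 (-1.04) and CLDN7 (-1.01) fell, KRT20 (2.05), CLDN3 (1.20) and AGR2 (0.63) rose, and 14 including KRT8 (0.11) did not pass (median 0.13, -0.68 without factors with 1 higher and 12 lower, and -0.03 with protein-coding genes only; camera adjusted p = 0.645). Of 20 WNT target genes, KREMEN1 (-1.29) was lower and LEF1 (1.12) higher (median 0.06, camera adjusted p = 0.342). LEF1 was not past the test without factors or without EV replicate 1 (adjusted p = 0.0874). The list median was -0.76 without factors, with 0 higher and 10 lower, and -0.09 with protein-coding genes only. CCND1, the most abundant WNT target, did not pass (0.92, edgeR adjusted p = 0.078). Over its alternatives the adjusted p ranged from 1.49e-05 (with a replicate block) to 0.837, and it was 0.000876 without cell replicate 1. Glycolysis genes were split (5 higher, 2 lower of 18; median 0.18, -0.64 without factors with 2 higher and 11 lower; camera adjusted p = 0.0723), with LDHB (1.70) and GAPDH (1.26) higher and ALDOC (-1.91) and the glucose transporter SLC2A1 (-1.37) lower. Zinc finger genes had 8 higher and 8 lower of 30 (median -0.23; ZNF8 -1.59, ZNF264 -1.57; camera adjusted p = 0.858).

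Of the markers of other cell types, the erythroid list was mostly called and the other 3 lists gave few calls. In the erythroid list HBA1, HBA2 (4.63, 8.23 ± 3.82 to 204 ± 117 CPM) and HBG2 (4.40) were higher, and those lower included SLC4A1 (-3.07) and GYPB, the latter with 72 counts over the cell libraries and listed at 0 in EVs (median -0.37 over 7 genes; camera adjusted p = 0.858). Liver and serum proteins had 1 lower of 5 (TF, -1.66; median -0.95), leukocyte and platelet markers 2 lower of 7 (CD68, -3.20, and ITGA2B, -1.58; median -1.21; 0 when adjusted over the list alone), and fibroblast and endothelial markers 1 lower of 6 (VWF, -1.72; median -0.79). Their camera adjusted p values were 0.359, 0.329 and 0.346. By fry the adjusted p was 0.0408, 0.106 and 0.00641, and 0.00641 for the erythroid list. These 4 lists were written to look for RNA of other cells, and CD68, ITGA2B and VWF did not pass in lane 1 alone. They also missed the threshold in 5, 4 and 3 of the 6 fits that left out a library (adjusted p up to 0.206, 0.277 and 0.141), and VWF with a replicate block (0.0545).

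In all, 17 of the 28 lists passed the camera threshold. Alternatives ended 6 of these calls: the EV biogenesis list passed in 10 of 15 (adjusted p 0.00132 to 0.626), immediate early genes in 12 (5.09e-05 to 0.647), splicing factors in 13 (1.33e-05 to 0.121), cytoskeleton genes in 13 (1.12e-06 to 0.0902), histones in 14 (2.56e-07 to 0.0658) and the proteasome in 14 (1.32e-08 to 0.0612). Of the lists that did not pass, ER chaperones passed in 5 of 15 (0.000657 to 0.403) and glycolysis in 4 (0.015 to 0.831). Cholesterol synthesis, WNT targets and erythroid markers passed in 1 each (0.0175, 0.0308 and 0.00673). Camera compared each list with all other tested genes, among them lncRNA genes (median -1.15) and pseudogenes (-1.06), whereas protein-coding genes had a median of 0.02. A protein-coding list can therefore come out higher without a shift among mRNAs. With protein-coding genes only, EV biogenesis (camera adjusted p = 0.299) and immediate early genes (0.106) lost their calls, and ER chaperones gained 1 (0.00271). The preset correlation treats the members of a list as nearly independent, which genes of 1 complex are not. With an estimated correlation none of the 28 passed, and the lowest adjusted p = 0.437 was shared by 7 lists, among them the ribosomal proteins. Fry, which tests against 0 on the TMM scale, passed some of these lists. Its adjusted p was 0.00283 for ribosomal proteins, 0.00641 for TOP mRNAs and for spliceosomal RNAs, and 0.00916 for mitotic genes. Others missed its threshold, among them sorting proteins (0.0593), splicing factors (0.0757), cytoskeleton genes (0.0757) and histones (0.0879).

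**Figure D3:**
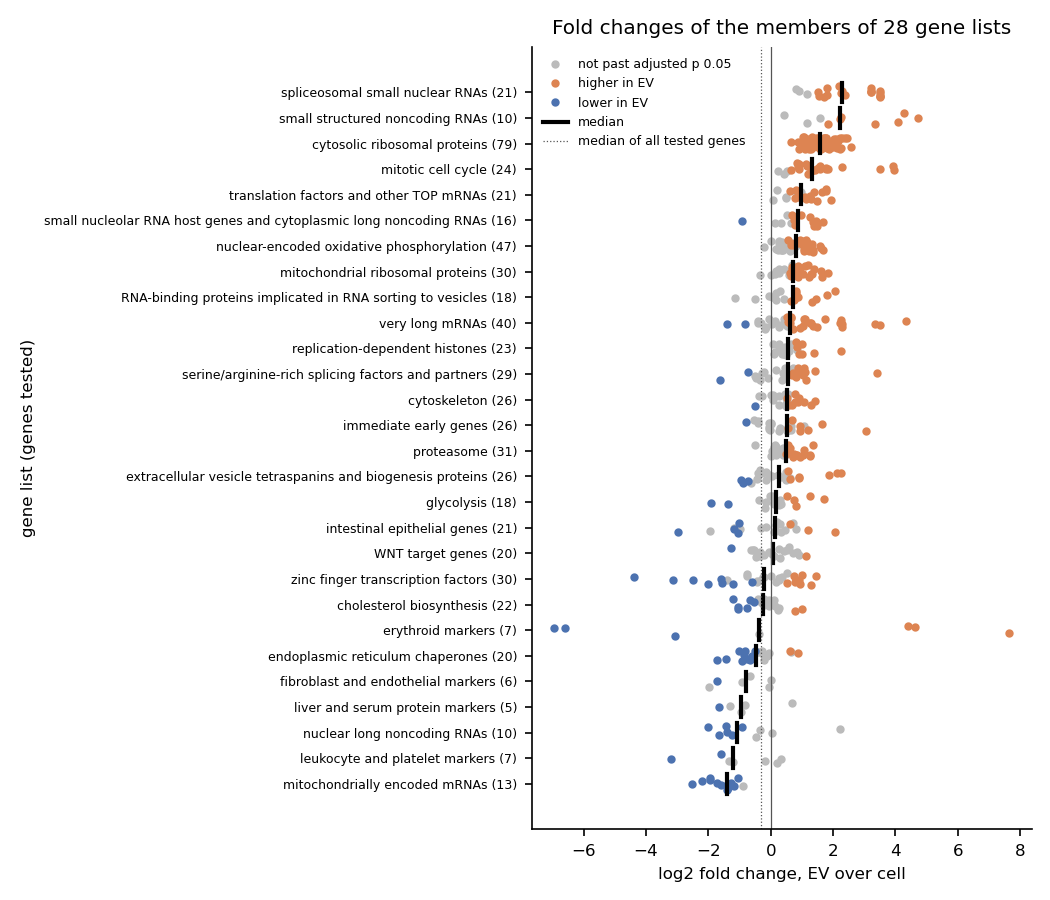
Each point is the log2 fold change (EV over cell) of 1 tested gene in 1 of 28 lists, coloured by whether it passed the adjusted threshold, with the list median as a bar and the median of all genes (-0.30) as a dotted line. Ribosomal proteins lie at a median of 1.57 and mitochondrially encoded mRNAs at -1.41; without scaling factors the medians move by about -0.81, and 12 lists from mitochondrial ribosomal proteins (0.70) down to WNT targets (0.06) turn negative.

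The median log2 fold change of protein-coding genes went down slightly with transcript length. Of 1665 protein-coding genes under 1000 nt, 448 were higher and 165 lower (median 0.29), whereas of the 205 longest genes 42 were higher and 43 lower (median -0.42). The 3 bins between had medians of 0.05, -0.04 and -0.13, but the share of genes called higher did not fall steadily over the 5 bins (26.9, 18.8, 22.2, 23.0 and 20.5%). The Spearman rho of log2 fold change with transcript length was -0.071 over 14500 genes and -0.059 without the ribosomal proteins (permutation p = 1e-05 each, two-sided, the smallest they can give). The TPM-weighted median length of protein-coding transcripts was 999 ± 91.5 nt in EVs and 1399 ± 106 nt in cells (n = 3 each, exact permutation p = 0.1). The rho is small. Long genes such as MACF1 and DST, and the fixed list of very long mRNAs (median 0.63), stood against the trend.

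Fewer distinct circRNAs were counted in EVs, a difference that did not pass the exact test used, which cannot go below 0.1 at this size. With every library thinned to 35072 back-splice reads, EV libraries showed 12133 ± 1842 distinct circRNAs and cell libraries 14636 ± 1020 (n = 3 each, exact two-sided permutation p = 0.1); unthinned, the numbers were 13551 ± 3540 and 22994 ± 1487. Among circRNAs with 2 or more reads the groups overlapped (exact permutation p = 0.2), with 10073 in EV library 2 and 9161 in cell library 2. Cell library 3, the RNase R library whose treatment field says Control, had a single read for 25.2% of its circRNAs. The other cell libraries had 58.1 and 57.1%. This difference is left unexplained, and whether it is linked to the label conflict is not known. Of 57616 distinct circRNAs in any library, 16895 were seen in both fractions, 1130 in all 3 cell libraries and no EV library, and 75 in all 3 EV libraries and no cell library. The 10 most read circRNAs took 3.40 ± 0.300% of back-splice reads in EVs and 5.43 ± 0.603% in cells (exact permutation p = 0.1).

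Single circRNAs differed in both directions. The circRNA of FAT1 exon 2 (3283 nt), FAT1 being an atypical cadherin, had the most reads of all and fell by 2.56 ± 0.25 on the log2 scale (13140 ± 3967 to 2222 ± 483 CPM; adjusted p = 3.63e-11, edgeR). The circRNAs of HIPK3 exon 2 (1099 nt, -0.94 ± 0.23) and SPECC1 exon 4 (1580 nt, -1.61) also fell, whereas those of ZBTB44 (1074 nt, -0.70, adjusted p = 0.0772) and ZKSCAN1 (578 nt, -0.05, adjusted p = 0.942) did not pass. Those highest in EVs came from COX5A (239 nt, 10.6 ± 9.31 to 162 ± 101 CPM), UPF1 (257 nt, 3.80), RAB6A (312 nt, 3.64), CHMP6 (285 nt, 3.64), FOCAD (319 nt, 3.52), KANSL1 (244 nt, 3.40) and 2 longer circRNAs of SMARCC1, a chromatin remodelling subunit (1324 nt, 3.52, and 1586 nt, 2.90). Those lowest came from HIVEP3 (5728 nt), LRRC8A (2165 nt), ZNF638 (1581 nt) and 2 loci, on chromosome 19 at 58260851 and on chromosome 22 at 42209651. The ends of these 2 loci were not matched to exon boundaries of a single transcript, so no host was assigned. All of these lowest circRNAs had 0 reads over the EV libraries. With a floor of 3 reads over the EV group they were at least 9.71-, 9.89-, 6.48-, 8.09- and 6.30-fold lower. SLC11A2 (1832 nt), OGA (1826 nt) and PRAG1 (2249 nt) had 53, 46 and 42 reads in cells and 1 read each in EVs.

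Of 1907 circRNAs tested, which held 45.5% of back-splice reads, 137 differed, 47 higher and 90 lower in EVs, and 380 had an unadjusted p under 0.05. The counts varied: DESeq2 gave 31 higher and 59 lower, and leaving out cell replicate 2 gave 16 and 54. Leaving out cell replicate 3, whose labels conflict, gave 18 and 83. Most calls at the high end rest on few cell reads (2 for COX5A), so their folds are imprecise; without the filter all 8 named as highest lost their calls, and 7 of them lost theirs when some single library was left out. UPF1 also lost it with DESeq2 (adjusted p = 0.0505), a replicate block (0.0985) and thinned libraries (0.063). Of those named as lowest, PRAG1 (0.0601) and the locus on chromosome 22 (0.0548) lost their calls without the filter, PRAG1 (0.0785) and the locus on chromosome 19 (0.099) in thinned libraries, and ZNF638, OGA, PRAG1 and the locus on chromosome 22 when some single library was left out. HIPK3 missed the threshold in thinned libraries (adjusted p = 0.0503, range 2.4e-08 to 0.0503 over its alternatives). ZBTB44 gained a call with a replicate block (0.0115), without the filter (0.0402), without EV replicate 3 (0.0158) and without cell replicate 1 (0.0381). Its adjusted p ranged from 0.0115 to 0.38 over its alternatives.

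Spliced length separated the circRNAs that were higher in EVs from those that were lower. The 47 higher ones had a median length of 301 nt (quartiles 264 and 353), and 44 were shorter than 500 nt. The lower ones had a median of 1776 nt (1188 and 2237), and 76 of the 86 with a known length reached 1000 nt; those not past the threshold had a median of 523 nt. From under 300 nt to over 2000 nt the median log2 fold change went from 0.87 over 0.34, -0.26 and -1.25 to -2.41. Spearman's rho was -0.66 over 1895 circRNAs, -0.837 over 204 with a single exon and -0.632 over 1691 with 2 or more, against -0.267 with exon number, -0.244 with genomic span and -0.109 with the mean length of the flanking introns (permutation p = 1e-05 each, two-sided, the smallest they can give). Per library, the read-weighted median length was 492.7 ± 20.1 nt in EVs and 658 ± 22.9 nt in cells, and circRNAs under 500 nt took 51.2 ± 2.68% of reads in EVs and 32.7 ± 1.32% in cells (n = 3 each, exact permutation p = 0.1). The circRNAs of SMARCC1 are the exceptions among the higher ones of 1000 nt or more.

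**Figure D4:**
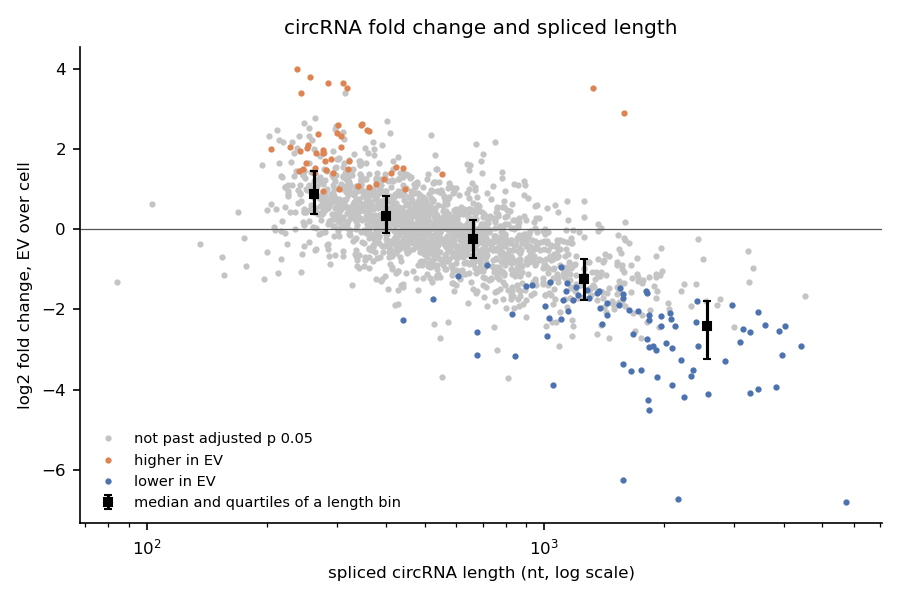
Each point is 1 of 1895 tested circRNAs, with its spliced length (nt, log axis) and its log2 fold change (EV over cell); black squares and bars give the median and quartiles of 5 length bins. Bin medians run from 0.87 under 300 nt to -2.41 over 2000 nt.

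No stable relation appeared between the circRNA and the linear fold change of a host gene. Across 2533 host genes with both values, the rho between circRNA and linear fold change was 0.023 (permutation p = 0.24, two-sided). With circRNA length held constant the partial rho was 0.092 (permutation p = 1e-05, the smallest it can give), and the plain rho was -0.08 without cell replicate 3 and 0.09 without cell replicate 1, so neither sign nor size is settled. Of 2538 host genes tested on summed back-splice reads, 40 were higher and 64 lower in EVs. Among those called in both kinds of library, 15 were higher in both, 5 lower in both, 27 lower as circRNA and higher as linear RNA, and 2 the reverse.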

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

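The thinned circRNA libraries, the single-exon circRNAs, the linear genes without ribosomal proteins and the partial correlation on circRNA length were tests chosen after the results were seen.

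No gene called in both settings changed direction with RLE factors, no factors, DESeq2, either lane, any filter or any library left out; limma on log2(TPM + 1) reversed 1784 calls. Counts of linear genes (differing, higher, lower) were 12430, 1104 and 11326 without factors and 19439, 196 and 19243 with limma on log2(TPM + 1), where the EV total is mostly 7SL RNA. A mean CPM of 10 or more gave 5012 differing and 2591 lower, and protein-coding genes only gave 2899 lower, both with fewer genes tested. Leaving out 1 library gave 5260 to 8691 differing, 2475 to 5153 higher and 1750 to 4396 lower. The lowest counts came without cell replicate 2 (5260 differing and 1750 lower) and, for lower genes, also without cell replicate 3 (2093); the cause was not tested. The share of higher genes among the calls was 44.6% in the report, 8.9% without factors and 1% on log2(TPM + 1).

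Of the genes that the naming rule takes, some not printed above, these rose on the TMM scale and had a negative value on log2(TPM + 1): EIF3E (-0.29), EEF1A1 (-0.88), NDUFB7 (-0.26), MRPL51 (-0.65), MRPL37 (-1.20), HIST1H1E (-0.44), HIST1H2AG (1.01 on the TMM scale, -0.81), SNHG8 (-0.29), GAS5 (-0.43), SNHG29 (-0.86), GAPDH (-0.61), LDHB (-0.38), PSMA3 (-0.59), PSMC6 (-0.64), ANXA2 (-0.07), SSB (-0.53), LEF1 (-0.92), SF3B1 (-1.31), MYL12B (-0.47) and TMSB10 (-0.77). Others stayed positive there but lost their call: RPS2 (0.03), MRPL41 (0.02), RPL37 (0.35), RPL12 (0.57), NACA (0.36), UQCRB (0.21), ANXA1 (0.20), YBX1 (0.36), FOSB (0.21) and DST (0.49). ATP5F1B (-1.56), HIST1H1C (-1.42), KRT8 (-1.63) and ZNF121 (-1.39) were lower on log2(TPM + 1). On the TMM scale these were not past the test (0.35, 0.42, 0.11 and 0.02). Without factors MRPL37 (-0.12), ATP5F1B (-0.47) and ZNF121 (-0.80) changed sign.

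Of 28 lists, 13 to 20 passed the camera threshold over the settings run, 17 in the report; DESeq2 and limma on log2(TPM + 1) were not run for lists. Over single lists and all settings but those leaving out a library, 14 values gained and 14 lost a call, and 214 did neither.

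Counts of circRNAs (differing, higher, lower) were 90, 31 and 59 with DESeq2, 78, 28 and 50 in lane 1, 76, 25 and 51 in lane 2, and 77, 31 and 46 in thinned libraries; lanes and thinned libraries hold fewer reads. With no filter 66 differed and 1 was higher, among 36057 circRNAs tested. Leaving out 1 library gave 70 to 157 differing, 16 to 46 higher and 54 to 111 lower. Without cell replicate 1, 2 or 3 the higher ones numbered 27, 16 and 18, without cell replicate 2 also 70 differed and 54 were lower, and without EV replicate 1 they numbered 31.

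The gap in the misc_RNA share was 57.6 percentage points on TPM against 26.8 on counts. The gap in distinct circRNAs was -2504 thinned, -9443 not thinned and -4412 for circRNAs with 2 or more reads, where the groups overlapped; neither of the last 2 is corrected for depth. The rho of circRNA and linear fold change of the host was 0.09 with length held constant; leaving out 1 library gave -0.08 (without cell replicate 3) to 0.09 (without cell replicate 1), with 0.06 without EV replicate 3, and the cause was not tested. The rho with circRNA length and that with transcript length kept sign and side of the threshold in every setting.

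The same-number libraries of cells and EVs showed no established pairing (correlations of deviations 0.157, 0.019 and 0.116 for genes, 0.066, -0.038 and 0.012 for circRNAs), against -0.129 to 0.046 between cell and EV control libraries of different number. Whether the numbers pair the samples stays open. With a replicate block, 8730 genes (4166 higher, 4564 lower) and 120 circRNAs (39 and 81) differed.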

Other observations

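The test of breakage at a constant rate, the test of reads shared between genes and the test among abundant solute carriers were chosen after the results they bear on were seen, and all patterns below were found in the same data that tested them.

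The fall of the circRNA fold change with spliced length was weighed first. Unequal depth is argued against, since the rho was -0.67 over 1152 circRNAs with every library thinned to equal reads. So are properties of the host gene as the whole cause: in 1264 pairs of circRNAs of 1 host, the longer one had the lower fold change in 73.7% (95% interval 70.6 to 76.8 over 374 hosts). Breakage at 1 rate per nucleotide as the sole cause would give equal slopes. The slope per 1000 nt was -2.31 below and -0.79 above 1000 nt, a difference of -1.52 (95% interval -1.82 to -1.24). Fold changes of some long circRNAs rest on 0 or 1 EV reads, and spliced lengths come from annotation. Either can flatten the slope above 1000 nt, so this test does not decide on breakage, which stays open. A limit on the size of circRNAs that enter or survive in EVs may contribute. Such a limit for RNA in general is not shown. For linear mRNAs the rho with length was -0.071 over 14500 genes, and MACF1 (4.34) and DST (3.36) were higher in EVs. The circRNA values come from RNase R libraries only. Losses that depend on length in EV isolation, RNase R treatment or library preparation stay open, because nothing in these data tests them.

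The 86 protein-coding genes with a log2 fold change of 3 or more, NET1, RAB13 and TRAK2 among them, were weighed next. After removal of a trend on GC content and length their median was 3.69 (95% interval 3.52 to 3.91, 81 genes), against 3.74 before. That trend held 7.6% of the variance over protein-coding genes, and the set was chosen for high fold changes. Its median could therefore hardly fall far, so a bias from GC content or length beyond this weak shared trend stays open. The median share of 31-mers found in other genes was 0.62% (85 genes), though 10 of these genes shared most of theirs. This argues against shared reads as the whole cause for the set. Purine-rich stretches were suspected from knowledge of NET1, RAB13, TRAK2 and KIF1C held before the data. Each gene was scored by the highest purine count of its 30 nt windows with at least 9 A and 9 G. A gene without such a window took the lowest possible score. Scores were compared with random sets matched on length (one-sided) but not on GC content. The mean score was higher by 1.27 in the 3' UTR (75 genes, permutation p = 0.019, 0.038 adjusted over 2 tests, 0.046 without those 4 genes). In the coding sequence it was higher by 0.62 (81 genes, permutation p = 0.046, 0.046 adjusted, 0.049 without them). Both differences mix the richness of windows with the share of genes that have a counted window. Across all genes the rho of log2 fold change was -0.13 with the 3' UTR score and 0.15 with the coding score. With GC content it was -0.34. A first run with exact transcript versions covered only 59 genes for the 3' UTR (difference 1.86). Since the random sets were not matched on GC content, base composition alone could give such differences. Whether such stretches mark this set, and their relation to the general ranking, stays open.

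Membrane and secretory mRNAs were weighed last. Solute carrier genes outside SLC25, made at the ER, had a median log2 fold change of -0.97 (3 higher and 75 lower of 216), whereas the 44 SLC25 genes, mitochondrial carriers made in the cytosol, had 0.07 (11 higher and 5 lower), a difference of -1.03 (permutation p = 1e-05, the smallest they can give, as for the next 2). It was -0.96 after removal of the trend on GC content and length and -1.08 among genes with a mean CPM of 10 or more. These values argue against low counts and against that trend as the cause. A bias from GC content or length beyond this weak trend stays open. mRNAs bound to the ER may enter EVs less often. Whether the ER itself, membrane anchoring or another trait of these genes is behind the difference was not tested.

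For both fits the 3 against 3 design gives 10 splits, too few for a share under 0.05: 1 split, the real one, gave 8048 genes and 137 circRNAs, and the highest other split gave 0 in each.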
